A study of Arabidopsis thaliana with 3 samples.

How the data were processed

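Small RNA sequencing of total RNA was deposited for 3 libraries, 1 each from WT, ddb2-3 and nrpd1a seedlings of Arabidopsis thaliana, 10 days old and grown in vitro. Genotypes were taken from the labels. For each library, 6 deposited tables give the level of 24-nt small RNAs over regions of differential DNA methylation, split by cytosine context (CG, CHG or CHH) and direction (hyper or hypo). Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and bedtools were used and the genome build was TAIR10. Per the file headers, the deposited values are RPM, that is, small RNA reads scaled to library size, summed over each region by the authors, and the regions come from bisulfite sequencing. The 24-nt length class and the class of a region are known only from the names of the deposited tables. The genotypes whose methylation was compared to define the regions, the reads that make up the RPM denominator, the mismatches allowed and the treatment of reads with several genomic hits are not given in the sources used here.

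Each library held 4849 entries, of which 271 repeated a region of the same class with the same value because it carried more than 1 annotation. After collapsing these there were 4578 regions in the 6 classes and 4481 distinct regions by coordinates. Within a class 76 regions overlapped another region of that class, and 194 class entries shared their coordinates with an entry of another class. Region widths ran from 51 to 800 bp with a median of 100 bp.

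The RPM values deposited by the authors were whole multiples of a single step per library, 0.169 RPM in WT, 0.120 RPM in ddb2-3 and 0.727 RPM in nrpd1a. With these steps 100.0% of the 4578 values of each library came out as whole reads within a tolerance of 0.1 read, the largest deviation being 0.00418 read. The steps correspond to normalising totals of 5913669, 8345931 and 1376238 reads. In fold bounds of single regions a level of 0 was set to a floor of 3 reads, 0.507 RPM in WT, 0.359 RPM in ddb2-3 and 2.18 RPM in nrpd1a, so that 1 nrpd1a read weighs more than 1 read of the other libraries. The 95% intervals of ratios are exact binomial (Clopper-Pearson) intervals on the recovered reads. For sums they treat reads as independent, although reads in overlapping regions are counted in each, so they are too narrow there. If reads with several genomic hits are counted at each copy, the intervals are too narrow over repeats as well. Floor bounds take the WT level as measured, so they lie above the lower bound of the exact interval. In the ATREP11 region named below the floor gives 172-fold and the interval 139-fold. Intervals cover counting error only, and floor bounds only that of the mutant.

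Both mutants were compared with WT in the same regions. Summed levels were compared as log2 ratios without a pseudocount. Per region, log2 ratios were computed as log2(RPM + 1) in the mutant minus the same in WT, which understates differences of weakly covered regions, among regions of at least 1 RPM in at least 1 library. A region was counted as higher or lower by size alone, at 2-fold or more on that scale, because 1 library per genotype allows no test of the genotypes. The median ratio of a class was placed among 10000 random lists of the same size, drawn from all distinct regions and matched on mean level in 10 bins. The 95% intervals of medians are binomial order-statistic intervals over regions, and those of differences between medians and of the GA repeat median come from 2000 bootstrap draws of regions, which are not replicates. The median ddb2-3 to WT ratio over the 4462 distinct regions with reads in both libraries was used as an alternative scaling. In simulated reads for all 4578 regions at the real depths, the size rule found 32.0% of 200 regions changed 2-fold and 95.0% of 200 changed 4-fold, with 0.32% and 0.251% of unchanged regions past it. An exact binomial count test on the recovered reads with Benjamini-Hochberg adjustment at 0.05, run as an alternative, found 58.5% and 90.0% of the same regions. The simulated reads vary by counting error alone, so the shares of unchanged regions are not error rates for the real libraries.

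Named regions were chosen by a rule fixed before the data were examined. Per class, among regions whose higher value of the 2 libraries was in the top 25% of the class, the rule took the 2 with the highest and the 2 with the lowest ddb2-3 to WT ratio, the 2 with the lowest nrpd1a to WT ratio and the 2 with the highest nrpd1a level. It also took each member of 5 gene lists with a region in its body or within 2 kb upstream. The lists covered RNA-directed DNA methylation and methylation factors, DNA demethylases, nucleotide excision repair and photolyase genes, known targets of DNA methylation, and TAS loci. Groups by gene context, by position within 3 Mb of the centromere (pericentromeric) or outside (arm), and by Pol IV dependence (at least 1 RPM in WT and under 10% of it in nrpd1a) were fixed beforehand as well. The Pol IV split is not compared for ddb2-3, because it is made on the WT level that is also the denominator of the ratio. The grouping of repeat families into superfamilies, the split of widths at 100 bp, the limit of 5 RPM for regions without reads, the sets of regions 4-fold higher or lower, the minimum of 5 regions per stratum and the gap of 5 kb that separates loci were chosen after the data were seen.

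Gene names and contexts came from the annotation of TAIR10.1, whose nuclear chromosome lengths equal those of TAIR10. Coordinates are those of the deposited tables. Of the gene entries listed for regions, 341 matched the annotation, 334 of them overlapped the gene, and 4 were not matched. Repeat family names are those listed with the regions. The number of genomic copies of each 24-mer of a region, 24-mers shared with the organelle genomes, inverted copies within 2 kb (BLAST+ 2.17.0, 100 bp or longer) and GA or CT repeats of 24 nt were computed from the same genome. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

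Alternatives were another pseudocount (0.1 or 10 RPM), no minimum level or one of 10 RPM, the median-ratio scaling, leaving out the 1% of regions with the highest mean level, and using only regions that overlap no other class. A further 4 were added after the data were seen, namely the count test, nrpd1a levels under 3 reads set to the floor with the pseudocount or without it, and leaving out regions with GA repeats. Transcripts of DDB2 and NRPD1 were not measured in these data, so the genotypes could be checked only through the siRNA levels. No methylation values were used here.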

Results

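The 3 libraries measured 24-nt small RNAs in 10-day-old Arabidopsis seedlings of WT, ddb2-3 and nrpd1a. DDB2 recognises damaged DNA in global genome repair. NRPD1 is the largest subunit of RNA polymerase IV (Pol IV), which starts the synthesis of most 24-nt siRNAs that direct DNA methylation. The study concerns repair factors and DNA methylation, so the comparison of ddb2-3 with WT asks how siRNA levels differ over differentially methylated regions without DDB2, and nrpd1a serves as the reference for loss of Pol IV siRNAs. Each genotype had 1 library, so no difference has a replicate check, and an interval or test on reads compares these libraries and not the genotypes.

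The regions comprised 33 CG-hyper, 48 CG-hypo, 1289 CHG-hyper, 708 CHG-hypo, 1758 CHH-hyper and 742 CHH-hypo regions, 4481 distinct ones in all. A repeat was listed for 4213 of them (94.0%). Gypsy LTR retrotransposons made up 53.0% of the CHG-hyper and 33.8% of the CHG-hypo regions, and 82.3% and 67.8% of these classes were pericentromeric. Helitrons, rolling-circle DNA transposons, made up 37.5% of the CHH-hyper and 44.9% of the CHH-hypo regions. Summed over the distinct regions there were 505585 reads in WT, 779644 in ddb2-3 and 4160 in nrpd1a. These sums equal 8.55%, 9.34% and 0.302% of the normalising total of each library. Distinct regions can overlap, and a read in an overlap counts in each, so the sums are not numbers of separate reads. The mean level per distinct region was 19.1 RPM in WT, 20.9 RPM in ddb2-3 and 0.675 RPM in nrpd1a.

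**Figure D1:**
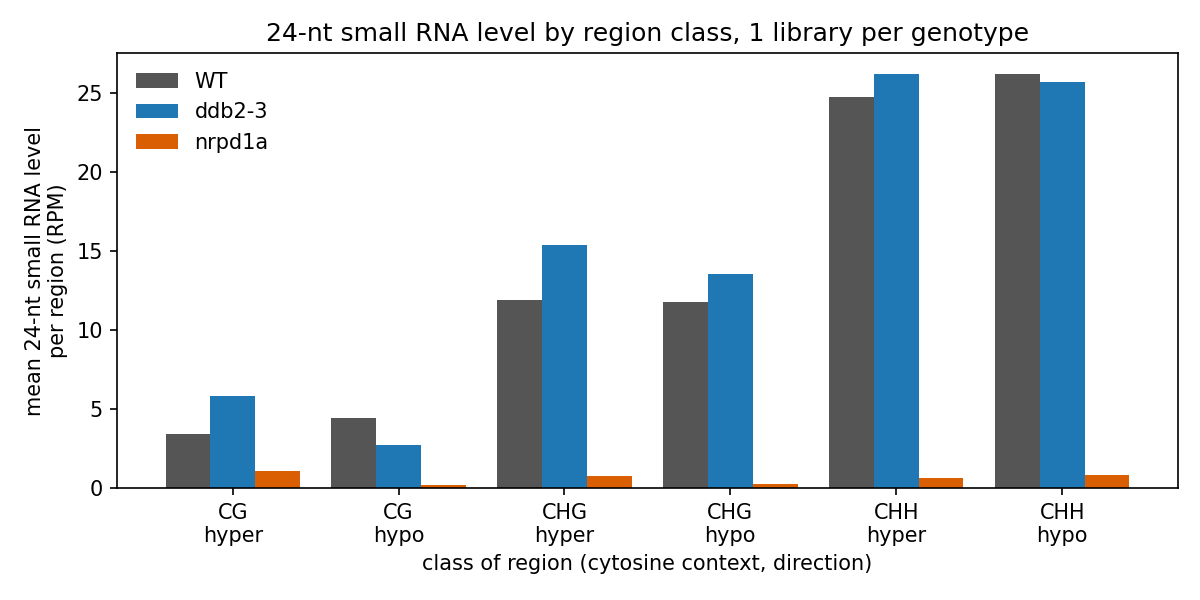
Mean 24-nt small RNA level per region, in RPM, for the 6 classes of regions, with 1 bar per library (WT, ddb2-3, nrpd1a). WT and ddb2-3 bars were highest in the CHH classes, at 24.8 to 26.3 RPM, and the nrpd1a bar was the lowest in each class.

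In the ddb2-3 library, summed siRNA levels over the CG-hyper and CG-hypo regions lay in opposite directions from WT. The CG-hyper regions had a mean of 3.44 RPM in WT and 5.88 RPM in ddb2-3, a log2 ratio of summed levels of 0.77 (95% interval 0.64 to 0.90), and the CG-hypo regions 4.47 and 2.74 RPM, a log2 ratio of -0.70 (-0.82 to -0.59). Of the 33 CG-hyper regions 22 were above WT. Regions at AT2G15340 and VANDAL1 held 5.41 and 7.78 of their 114 RPM in WT, and 21.8 and 23.6 of 194 RPM in ddb2-3. Over regions overlapping no other class the CG-hyper and CG-hypo sums were 0.60 and 0.12, so their directions no longer differed. CHG-hyper regions were also higher in ddb2-3, at 0.37 (0.36 to 0.38), and Gypsy retrotransposons were the main repeat group among them. The CHG-hypo sum was 0.20 (0.19 to 0.22), the CHH-hyper sum 0.083 (0.075 to 0.090) and the CHH-hypo sum -0.028 (-0.039 to -0.017), which becomes 0.030 without the 1% highest regions. The median distinct region was 0.20 higher in ddb2-3 on the log2 scale, so values are also given relative to it. Relative to that region the sums were 0.57 for CG-hyper, -0.90 for CG-hypo, 0.17 for CHG-hyper and 0.0025 for CHG-hypo, while CHH-hyper turned to -0.12 and CHH-hypo lay at -0.23.

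Counted by region, CG-hypo had the largest share of lower regions. Of the 48 CG-hypo regions, 22 were at least 2-fold lower and 2 at least 2-fold higher in ddb2-3, and of the 33 CG-hyper regions 8 were higher and 1 was lower. Among CHG-hyper regions 102 were higher and 3 lower, among CHG-hypo 39 and 34, among CHH-hyper 63 and 9, and among CHH-hypo 26 and 13. Relative to the median region the CHG-hypo and CHH-hypo counts turned, with 23 higher and 39 lower and with 13 higher and 19 lower, and the CHG-hyper counts were 55 and 4. The median log2 ratio was 0.45 (-0.014 to 0.78) for CG-hyper, -0.80 (-1.34 to -0.33) for CG-hypo, 0.34 (0.31 to 0.39) for CHG-hyper and 0.21 (0.14 to 0.27) for CHG-hypo. For CHH-hyper it was 0.088 (0.066 to 0.12), which becomes -0.083 relative to the median region. For CHH-hypo it was 0.0089 (-0.022 to 0.053), which becomes -0.17. The CG-hypo median becomes 0.46 over its regions of at least 10 RPM in at least 1 library. That limit can be met through ddb2-3 alone, as by an ATHILA4 region with 6.76 RPM in WT and 16.1 RPM in ddb2-3. Only 5 CG-hypo regions had at least 10 RPM in WT. The turn thus rests on few regions, chosen in part on the ddb2-3 level. Against 10000 random lists matched on level, the CG-hypo, CHH-hyper and CHH-hypo medians lay at percentile 0.0, and the CG-hyper, CHG-hypo and CHG-hyper medians at percentiles 98.6, 90.1 and 100. The CG-hypo sum rested on regions that also belong to another class: 25 of the 48 overlapped a CHG-hypo region, and over the regions that overlapped no other class the sum was 0.12, before the median-ratio scaling that lowers it by 0.20. The median of those regions was still -0.33, with 2 higher and 7 lower.

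The lowest regions of the ddb2-3 library were mostly transposons of the chromosome arms. The largest difference lay in an ATREP11 Helitron on chromosome 2 (14653601 to 14653800), a CHG-hypo region 357 bp from AT2G34730. It had 61.7 RPM in WT and no read in ddb2-3, at least 172-fold lower by the floor and 139-fold by the exact interval. Its CHH-hypo part (14653601 to 14653700) was at least 162-fold lower by the floor and 131-fold by the interval. Further bounds for regions without a ddb2-3 read are by the floor. An ATREP1 Helitron on chromosome 2 (13702401 to 13702600) went from 44.1 RPM to no read, at least 123-fold lower. In the CG-hypo class an ATREP4 Helitron on chromosome 3 (8785101 to 8785400), 648 bp from AT3G24240, a gene for a leucine-rich repeat receptor-like kinase, had 8.12 RPM in WT and no read in ddb2-3, at least 22.6-fold lower. A TA11 element, a LINE-type retrotransposon in an exon of the transposon gene AT1G29650 (chromosome 1, 10363101 to 10363358), had 35.7 RPM in WT and 15 reads in ddb2-3 in its CHH-hypo region, 19.9-fold lower (11.8 to 36.1), and its CG-hypo part (10363101 to 10363200) was 24.5-fold lower (7.92 to 122) on 3 ddb2-3 reads. In nrpd1a these regions held 0 reads, or 2 reads in ATREP11. CG-hypo Helitrons had a summed log2 ratio of -1.79 (-2.04 to -1.54) with 12 of 18 regions lower, and the 4 CG-hypo LINE regions one of -2.06 (-2.45 to -1.69).

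Regions of the hyper classes named as lowest differed less, but the rule took them only from the top 25% of each class by level. The 1 CG-hyper, 3 CHG-hyper and 9 CHH-hyper regions at least 2-fold lower are not among them. In CHH-hyper, an ATREP8 Helitron 42 bp from PDLP6, a gene for a plasmodesmata-located protein (chromosome 2, 292730 to 292800), had a ratio of 0.488 (0.398 to 0.598), and VANDAL22, a Mutator-like element (chromosome 2, 14458501 to 14458571), one of 0.535 (0.462 to 0.62). In CHG-hyper, VANDALNX2 (chromosome 1, 12476901 to 12477000) had a ratio of 0.581 (0.445 to 0.758) and ATDNA12T3_2 (chromosome 3, 13859301 to 13859400) one of 0.616 (0.579 to 0.655), from 374 RPM in WT. In CG-hyper, ATGP1 (chromosome 4, 1622101 to 1622200) at 0.848 (0.575 to 1.25) and ATHILA6B (chromosome 1, 15048001 to 15048100) at 0.989 (0.657 to 1.50) could not be told from 1 at this depth.

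The regions named as highest in ddb2-3 included coding exons and repeats. LCR26 (AT4G29290), which encodes a low-molecular-weight cysteine-rich protein, had a CHG-hyper region over part of its coding exon (chromosome 4, 14432740 to 14432900) with 0.845 RPM, or 5 reads, in WT and 23.8 RPM in ddb2-3, 28.2-fold higher (11.9 to 87.8). The glycine-rich protein gene AT2G15340 had a CG-hyper region over part of its coding exon (chromosome 2, 6677501 to 6677700) with 5.41 RPM in WT and 21.8 RPM in ddb2-3, 4.03-fold higher (2.76 to 6.07), and a CHG-hyper region containing it (6677401 to 6677700) was 4.14-fold higher (2.83 to 6.23). A VANDAL1 element 1154 bp from AT2G05540, another glycine-rich protein gene (chromosome 2, 2031801 to 2032000), was 3.03-fold higher (2.19 to 4.28). Among hypo regions, ATHILA4 in AT4G06581 (chromosome 4, 3568701 to 3568800) was 2.37-fold higher (1.66 to 3.47), ATHILA2 in AT4G06624 (chromosome 4, 3740701 to 3740800) 1.69-fold (1.25 to 2.31), a region in the coding exon of AT3G44006 (chromosome 3, 15796237 to 15796400) 2.64-fold (1.87 to 3.78) and ATHILA2 near AT2G09900 (chromosome 2, 3752201 to 3752300) 2.65-fold (1.84 to 3.89). The 4 named CHH regions all contained a GA repeat: ATCOPIA68 in an intron of ARF23, an auxin response factor gene (chromosome 1, 16673531 to 16673695), had 42.8 RPM in WT and 218 RPM in ddb2-3, VANDAL21 (chromosome 2, 3110501 to 3111000) had 66.1 and 325 RPM, ATDNAI27T9C 132 bp from AT3G42060 (chromosome 3, 14254401 to 14254500) 23.0 and 126 RPM and LIMPET1 (chromosome 2, 4650263 to 4650400) 27.2 and 146 RPM.

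By repeat type, Gypsy retrotransposons stood above the other groups in ddb2-3. Over 1240 distinct Gypsy regions the summed log2 ratio was 0.47 (0.46 to 0.48), or 0.27 relative to the median region, and 108 regions were at least 2-fold higher and 1 lower, or 51 and 3 relative to it. Of the Gypsy regions, 78 had at least 90% unique 24-mers. If reads shared between copies are counted at each, the interval is too narrow and the regions are not separate observations. The summed Gypsy ratio was above 0 in each of the 6 classes, at 0.59 in CG-hyper, 0.62 in CG-hypo, 0.53 in CHG-hyper, 0.50 in CHG-hypo, 0.37 in CHH-hyper and 0.43 in CHH-hypo, and stayed above 0 under the median-ratio scaling. Among Gypsy families ATHILA ones had the highest sums, with 0.70 for ATHILA6B, 0.68 for ATHILA6A and 0.58 for the 313 ATHILA2 regions. ATGP2 at 0.41 and ATLANTYS1 at 0.36 lay near the lowest ATHILA families, ATHILA4A and ATHILA4C, both at 0.38. ATGP1 had 0.17, which becomes -0.032 relative to the median region, and ATLANTYS2 -0.014. Helitrons had -0.040 (-0.049 to -0.031), with 14 regions higher and 36 lower. Mutator-like elements had 0.046, turning to -0.15 relative to the median region, and Copia elements -0.073. The Mutator-like family VANDAL21 had the highest sum of all families of at least 20 regions, 1.36 (1.28 to 1.43), and 2 of its 24 regions, both with GA repeats, held 325 and 193 of its 745 RPM in ddb2-3.

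**Figure D2:**
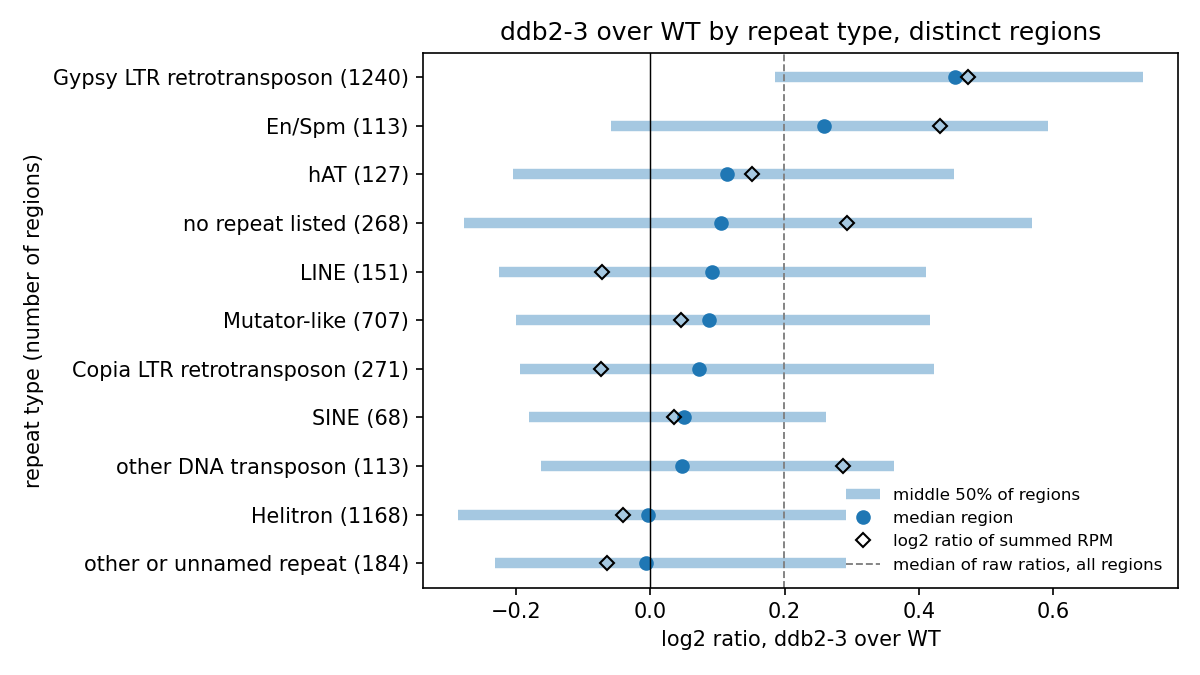
Log2 ratio of ddb2-3 over WT for distinct regions grouped by listed repeat type, with the number of regions in parentheses, where points are median regions on the log2(RPM + 1) scale, bars the middle 50% of regions, diamonds the log2 ratio of summed RPM, and the dashed line at 0.20 the median of the raw ratios of all regions. Gypsy regions had the highest median, 0.45.

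Position along the chromosome went with the ratio. The 2668 pericentromeric regions had a summed log2 ratio of 0.30 (0.29 to 0.31) with 175 regions higher and 23 lower, and the 1813 arm regions -0.049 (-0.057 to -0.042) with 59 higher and 52 lower. Gypsy regions near the centromeres reached 0.49, and the 51 Gypsy regions of the arms 0.15, which becomes -0.045 relative to the median region. The other pericentromeric regions had 0.13, turning to -0.065. CG-hypo regions of the arms were at -1.74 (-1.95 to -1.53), with 15 of 26 lower, and those near the centromeres at -0.11 (-0.26 to 0.042). The CG-hyper median, in place of the sum, was -0.041 over 13 arm regions and 0.59 over 20 near the centromeres. The CHG-hypo sum was -0.20 in the arms and 0.36 near the centromeres. The CHG-hyper sums were 0.19, or -0.014 relative to the median region, and 0.41. By gene context, regions in pseudogenes or transposon genes had a median of 0.32 over 1434 regions, and those within 2 kb upstream of a gene 0.076 over 1712 regions, which turns to -0.10 relative to the median region.

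**Figure D3:**
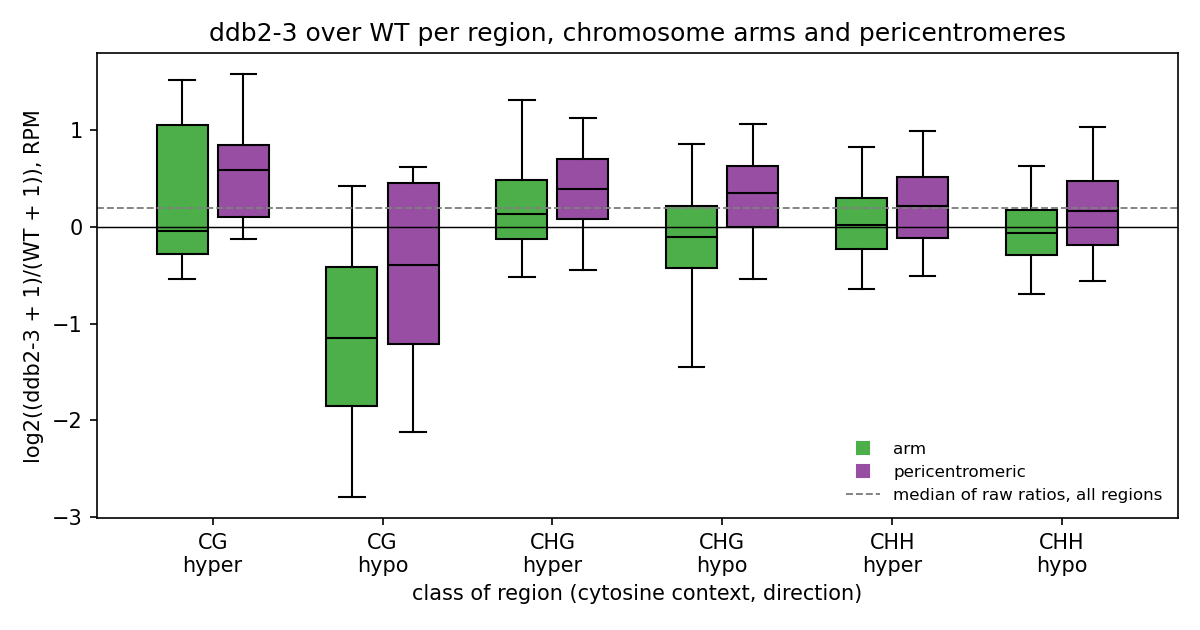
Log2((ddb2-3 + 1)/(WT + 1)) of RPM per region by class, for chromosome arms and pericentromeric regions, where boxes span the quartiles with the median as a line, whiskers run from the 5th to the 95th percentile, and the dashed line at 0.20 is the median of the raw ratios of all regions. CG-hypo regions of the arms had the lowest median, -1.15.

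The nrpd1a library held few 24-nt siRNAs over these regions. Over all distinct regions it kept 3.54% (3.43 to 3.65) of the WT level, and 3454 of 4481 regions (77.1%) had no read. By class it kept 4.07% (2.10 to 7.13) in CG-hypo, 6.62% (6.28 to 6.98) in CHG-hyper, 2.24% (1.98 to 2.54) in CHG-hypo, 2.66% (2.53 to 2.80) in CHH-hyper and 3.31% (3.09 to 3.54) in CHH-hypo, and 32.0% (23.5 to 42.7) in CG-hyper. The CG-hyper and CHG-hyper values rested on few regions: 2 CG-hyper regions held 32 and 16 of 50 reads and 29 of 33 had no read, and 2 CHG-hyper regions held 637 and 272 of 1401 reads. Without the 1% highest regions the log2 ratio of the CHG-hyper sum was -4.71 in place of -3.92. Of the 4270 regions with at least 1 RPM in WT, 3925 (91.9%) were under 10% of WT, and of the 1012 whose WT level was high enough for 3 nrpd1a reads to fall under 10%, 978 (96.6%) were. By the 2-fold rule 4162 regions were lower and 11 higher in nrpd1a, and 2552 were lower by the same rule with nrpd1a levels under 3 reads set to the floor. With that floor and no pseudocount 2805 were lower, the median region of at least 1 RPM in WT was at least 3.41-fold lower, and that of at least 10 RPM at least 10.9-fold lower.

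Transposons of several types were among the regions with the largest loss. ATDNAI27T9A on chromosome 5 (9069301 to 9069400) had 441 RPM in WT and no read in nrpd1a. It was at least 202-fold lower by the floor and 164-fold by the exact interval, and the bounds that follow are by the floor. A region of ATREP10D and ATREP13 Helitrons on chromosome 2 (6629801 to 6629900) went from 320 RPM in WT to no read, at least 147-fold lower, and ATMU3N1 in an untranslated exon of AT5G19210 (chromosome 5, 6461201 to 6461285) was at least 113-fold lower. RP1_AT, 116 bp from AT1G55430 (chromosome 1, 20699803 to 20700000), had 341 RPM in WT and 1 read in nrpd1a, and ATREP2 near the receptor-like protein gene RLP45 (chromosome 3, 19740201 to 19740300) 207 RPM and 1 read. ATHILA3 in AT5G34842 (chromosome 5, 13025901 to 13026000) was at least 81.7-fold lower, and ATGP1 copies in AT4G03650 (chromosome 4, 1621401 to 1621500) and AT4G10580 (chromosome 4, 6533301 to 6533600) at least 55.5-fold and 51.0-fold. In the CG classes, where WT levels were low, the named bounds were smaller, from at least 4.65-fold for ATHILA2 (chromosome 5, 12342101 to 12342200) and 5.28-fold for ATHILA4A (chromosome 1, 15754101 to 15754200) to 6.21-fold for ATLINE1_6 (chromosome 2, 2273801 to 2274110) and 6.75-fold for ATLINE1_1 (chromosome 1, 25343801 to 25343969).

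The regions named for the highest nrpd1a level included some at or above their WT level in RPM. The reads in the RPM denominator are not known and nrpd1a was not rescaled, so these ratios hold on the RPM scale only. ATDNA12T3_2 copies on chromosome 3 had 463 RPM in nrpd1a (13763401 to 13763455), a ratio to WT of 1.81 (1.65 to 1.99), and 228 RPM against 138 RPM in WT (13796043 to 13796100), a ratio of 1.66 (1.45 to 1.89). AT2G07732, annotated for the catalytic domain of the rubisco large chain (chromosome 2, 3468501 to 3468600), had 198 RPM in nrpd1a against 4.90 RPM in WT, 40.3-fold higher (27.4 to 61.3), and 80.5% of its 24-mers also occur in an organelle genome. AT3G44580 (chromosome 3, 16160801 to 16160900) had 155 RPM in nrpd1a, 165 RPM in WT and 241 RPM in ddb2-3, and its neighbouring CHG-hypo region (16160901 to 16161000) 54.5, 45.0 and 58.1 RPM. AT1G66290, an F-box gene (chromosome 1, 24714701 to 24714800), had a ratio of 1.20 (0.833 to 1.70). BRODYAGA2 near MYB53 (chromosome 5, 26069901 to 26070000) had 0.683 (0.498 to 0.92) and ARNOLDY2 (chromosome 3, 14737201 to 14737500) 0.522 (0.315 to 0.823). In CG-hyper, 2 regions in coding exons of the tetratricopeptide and pentatricopeptide repeat genes AT1G63130 (chromosome 1, 23413701 to 23413800) and AT1G63080 (chromosome 1, 23389801 to 23389900) held 32 and 16 reads, with ratios of 19.6 (8.52 to 52.7) and 5.73 (2.54 to 13.3). The CG-hypo regions named for the highest nrpd1a level, in an intron of AT3G42870 (chromosome 3, 14949601 to 14949700) and near RIK (chromosome 3, 11288246 to 11288400), held 1 read each. By gene context nrpd1a kept 1.33% of the WT level in pseudogenes and transposon genes, 2.03% upstream of genes and 10.2% in protein-coding genes, where 3 regions held 272, 214 and 75 of the 922 reads. The 18 regions in non-coding RNA genes held 79 nrpd1a reads, 55 of them in 1 region with a tRNA-Cys gene.

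Set side by side, the mutants differed in their overall level. The ddb2-3 library held 109% of the WT level over all distinct regions, a log2 ratio of 0.13 that turns to -0.071 relative to the median region, with 15 regions without a read, against 3.54% and 3454 regions in nrpd1a.

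Few members of the gene lists had a region, and none of those regions passed the 2-fold rule on the log2(RPM + 1) scale between ddb2-3 and WT. Of 23 methylation factors, 4 had one upstream: NRPD1 with a ratio of 1.03 (0.659 to 1.64), HEN1, the small RNA methyltransferase, with 1.04 (0.831 to 1.30), SUVH9, which recruits polymerase V to methylated DNA, with 0.735 (0.624 to 0.865), and the CG methyltransferase gene MET1 with 0.386 (0.117 to 1.14) on 11 and 6 reads. The NRPD1 region held no read in nrpd1a. Among 14 excision repair and photolyase genes, UVR2, the photolyase for pyrimidine dimers, had 2 upstream regions, with ratios of 0.816 (0.618 to 1.08) and 0.784 (0.641 to 0.96). Among 15 known targets of DNA methylation, AGL36 had 0.841 (0.41 to 1.75), and the homeodomain gene HDG9 had 2 overlapping coding-exon regions with 0.502 (0.253 to 0.974) and 0.472 (0.222 to 0.974), from 4.06 to 2.04 RPM in the wider one. Of 5 TAS loci TAS1B had an upstream region, at 1.05 (0.688 to 1.60), and none of the 4 DNA demethylase genes had one.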

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

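The count test, the floor of 3 reads for nrpd1a with and without the pseudocount, and the leaving out of GA repeats were chosen after the data were seen, and the other alternatives before. Of the values that answer a comparison, 129 stayed within their interval or within 1.5 times the main count, 124 lay outside it with the same direction and 5 changed direction. Of the values for named regions and for regions higher in nrpd1a, 98 stayed and 52 moved, and none changed direction. All values without a minimum level, and all sums over regions of at least 1 RPM, stayed. These settings are no check, since 4480 of the 4481 distinct regions had at least 1 RPM in at least 1 library. Leaving out GA repeats could not change the CG and CHG classes, which held no such region. The values counted as staying include these. Depth limits chiefly nrpd1a, where 1 read is worth 0.727 RPM. Where several values follow each other, the classes are in the order CG-hyper, CG-hypo, CHG-hyper, CHG-hypo, CHH-hyper and CHH-hypo. Unless construction is named, the cause was not tested.

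With the median-ratio scaling, the summed log2 ratios of ddb2-3 were 0.57, -0.90, 0.17, 0.0025, -0.12 and -0.23, with a change of direction for CHH-hyper. The medians were 0.17 and 0.043 for CHG-hyper and CHG-hypo and -0.17 for CHH-hypo, and CHH-hyper changed direction to -0.083. Regions 2-fold higher numbered 5, 0, 55, 23, 41 and 13, against 8, 2, 102, 39, 63 and 26, and lower ones in CHH-hyper 15 against 9. By construction this scaling lowers each summed log2 ratio by the same amount.

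Over regions overlapping no other class, the ddb2-3 sum changed direction for CG-hypo, to 0.12, and was 0.60 for CG-hyper, 0.40 for CHG-hyper and 0.26 for CHG-hypo. The count of higher regions was 5 for CG-hyper, that of lower regions 7, 18 and 7 for CG-hypo, CHG-hypo and CHH-hypo against 22, 34 and 13. In nrpd1a the sums were -1.15, -3.80 and -3.77 for CG-hyper, CG-hypo and CHG-hyper, and 20 CG-hypo regions were lower against 44.

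Without the 1% highest regions the CHH-hypo sum of ddb2-3 changed direction to 0.030, and the sums of CHG-hyper and CHH-hyper were 0.40 and 0.11. For nrpd1a they were -4.71, -5.37 and -5.06 in CHG-hyper, CHH-hyper and CHH-hypo. Without regions holding GA repeats, the ddb2-3 sums were 0.053 in CHH-hyper and -0.054 in CHH-hypo.

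With a minimum level of 10 RPM in at least 1 library, which leaves fewer regions, the ddb2-3 median of CG-hypo changed direction to 0.46. The medians of CG-hyper, CHG-hyper and CHG-hypo were 1.10, 0.44 and 0.30. The ddb2-3 level itself counts toward this minimum, and only 2 CG-hyper and 5 CG-hypo regions had 10 RPM in WT. The counts of higher regions were 5, 1, 32, 13, 27 and 12, and of lower regions 0, 2, 0, 10, 0 and 5 against 1, 22, 3, 34, 9 and 13. For nrpd1a the medians were -2.96, -3.52, -3.97, -4.04, -4.15 and -4.19, against -1.82, -2.08, -2.39, -2.56, -3.11 and -3.08. Regions lower in nrpd1a numbered 6, 7, 488, 260, 939 and 390 against 26, 44, 1168, 663, 1650 and 700. The share under 10% of WT in nrpd1a at 10 RPM in WT was 100% in both CG classes, 97.1% in CHG-hyper, 95.3% in CHH-hyper and 92.8% in CHH-hypo, against 86.2%, 91.3%, 95.2%, 90.01% and 88.4%.

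A pseudocount of 0.1 RPM gave ddb2-3 medians of -1.53 for CG-hypo and 0.41 for CHG-hyper, and nrpd1a medians of -4.72, -4.97, -5.19, -5.32, -5.49 and -5.44. Higher regions in ddb2-3 numbered 199, 83, 133 and 49 in the CHG and CHH classes, and lower ones 20, 31 and 31 in CHG-hyper, CHH-hyper and CHH-hypo. A pseudocount of 10 RPM, which by construction shrinks ratios of low regions, gave ddb2-3 medians of -0.16, 0.14, 0.077 and 0.049 for CG-hypo, CHG-hyper, CHG-hypo and CHH-hyper, and nrpd1a medians of -0.33, -0.40, -0.53, -0.59, -0.92 and -0.90. Counts were then 1, 0, 4, 0, 9 and 3 higher and 0, 1, 0, 4, 0 and 3 lower in ddb2-3, and 2, 4, 367, 205, 827 and 344 lower in nrpd1a.

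The count test, an exact binomial test on the recovered reads with Benjamini-Hochberg adjustment, counts differences of any size and called 356, 138, 287 and 84 regions higher and 24, 60, 139 and 84 lower in ddb2-3 in the CHG and CHH classes, against 102, 39, 63 and 26 higher and 3, 34, 9 and 13 lower by size. With nrpd1a levels under 3 reads set to the floor and the pseudocount kept, 8, 16, 594 and 341 regions of the CG and CHG classes were 2-fold lower in nrpd1a, against 26, 44, 1168 and 663. With the floor and no pseudocount, which changes both choices, they were 9, 18, 664 and 395.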

Other observations

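The tests of library scaling, of GA repeats and of inverted copies by family, the sets of regions 4-fold higher or lower and the repeat families described here were chosen after the results were seen. The other tests were set before the result they measure was seen, except that the matched inverted-copy comparison replaced a first, unmatched one.

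The 4-fold lower and the 4-fold higher regions of ddb2-3 were unlike each other. The 21 regions 4-fold lower formed 12 loci, all in hypo classes and 16 of the regions in chromosome arms, and in each at least 95.3% of the 24-mers occur once in the genome. They included ATCOPIA23 in the transposon gene AT3G60170 (chromosome 3, 22232501 to 22232700), 6.76 RPM in WT and 0.120 RPM in ddb2-3, ATLINE1_6 (chromosome 2, 2273601 to 2274110), 14.0 and 1.32 RPM, and ATREP5 192 bp from AFH14, a formin gene (chromosome 1, 11407001 to 11407300), 3.21 RPM and no read. A region in a coding exon of AT4G16195 and in an untranslated exon of AT4G16190, a papain-family protease gene (chromosome 4, 9173301 to 9173600), had 5.41 RPM in WT and no read in ddb2-3. Of the 15 distinct regions without a ddb2-3 read, 7 had at least 5 RPM in WT, and of the 4 without a WT read, 0 had that level in ddb2-3. The 7 are not separate loci, since the ATREP11, ATREP1 and ATREP4 regions each occur in 2 classes with overlapping coordinates. The 11 regions 4-fold higher lay at 10 loci, and 2 of them, in LCR26 and in the F-box gene AT1G32140 (chromosome 1, 11564701 to 11564800, 1.01 RPM in WT and 8.87 RPM in ddb2-3), held no GA repeat.

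Regions with nrpd1a reads belonged to several repeat families and to no listed repeat. Among regions listing a single repeat family, at least 10 nrpd1a reads were found in 8 of 46 regions of ARNOLDY2 and 4 of 42 of ARNOLDY1, both Mutator-like, in 5 of 115 of the Helitron HELITRONY3, in 5 of 144 of the Gypsy element ATGP1 and in 3 of 17 of ATDNA12T3_2, where these 3 held 463, 228 and 63.2 of the 765 RPM in nrpd1a. The ATGP1 regions together kept 2.39% of the WT level, less than the 3.54% over all regions. Of the 268 regions without a listed repeat 8 had at least 10 reads, and of the 583.5 RPM that all 268 held in nrpd1a, 198, 155 and 54.5 RPM lay in AT2G07732 and 2 adjacent regions of AT3G44580. Examples were ARNOLDY2 in an intron of GSL09, a callose synthase gene (chromosome 5, 14525201 to 14525300), with 13.2 RPM in WT and 13.1 RPM in nrpd1a, and HELITRONY3 in an intron of AT1G33950 (chromosome 1, 12337101 to 12337200), with 7.61 and 13.1 RPM. A region with tRNA-Cys gene AT5G20856 (chromosome 5, 7074301 to 7074400) had 3.38 RPM in WT and 40.0 RPM in nrpd1a.

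The CHG classes differed from each other by a median log2 ratio of 0.13 (bootstrap interval 0.055 to 0.21), hyper above hypo, at 0.23 (0.14 to 0.33) in the arms and 0.040 (-0.013 to 0.096) near the centromeres. In 2 tests set beforehand, a difference above 0.05 at the lower bound was required. The difference was 0.084 (0.027 to 0.13) within strata of superfamily and position, and 0.11 (0.046 to 0.24) among regions of at least 100 reads, so neither test decided, and no explanation is weighed. The GA repeats were taken up in place of this difference after the sequences of the highest regions had been seen.

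Gypsy regions were higher in ddb2-3. The tables argue against the 3 Mb pericentromeric window as the whole cause of their difference from other regions. After median-ratio scaling the summed log2 ratio was still 0.27 (0.26 to 0.28). That value followed from the sum and the median ratio already known, so it is no separate test. By construction 1 scaling factor shifts all repeat types alike, so it cannot set Gypsy regions apart from the other types. Whether Gypsy levels rose or those of other types fell cannot be told, as the reads in the RPM denominator are not known. Among pericentromeric regions the Gypsy median exceeded that of the others by 0.30 (0.26 to 0.34). That interval treats regions as separate, although repeat copies may share reads. Distance to the centromere within the window was not held alike, and it holds 1189 of the 1240 Gypsy regions. Position may still contribute, since the 51 Gypsy regions of the arms had a sum of -0.045 relative to the median region. Reads shared between repeat copies stay open: among regions with at least 90% unique 24-mers the difference was 0.21 (0.056 to 0.33), over 78 Gypsy and 668 other regions, with a lower bound under the 0.1 that had been required. An effect of the ddb2-3 genotype stays among the explanations and was not tested, since there was 1 library.

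Regions 4-fold higher in ddb2-3 may largely reflect reads of GA repeats counted at many regions. All 14 distinct regions with a 24-mer of GA repeats, found by sequence alone, had a median log2 ratio of 2.21 (1.65 to 2.28). Of these 14 regions, 13 were at least 2-fold higher, against 221 of the 4466 others. If the same reads are counted at many of the 14, these are not separate observations, and the interval and the count carry little weight. On chromosome 1 the regions 16673501 to 16673700 and 16673531 to 16673695 also overlap. The idea came from regions of the 4-fold higher set and 9 of the 14 belong to that set, so it is a hypothesis found on the same data. The 14 regions together held 416.5 RPM in WT, 1704 RPM in ddb2-3 and 1.45 RPM in nrpd1a, where 12 had no read. Whether the GA reads differ with the genotype was not tested, since there was 1 library.

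Signal kept in nrpd1a may come in part from inverted repeats, whose hairpin transcripts need no polymerase IV. An inverted copy within 2 kb was found for 51.2% of the 43 regions with at least 10 nrpd1a reads and for 3.72% of 430 regions without nrpd1a reads matched on WT level, 10 to each. Counted by loci the shares were 51.2% of 41 and 3.55% of 366, and the matching replaced a first comparison with unmatched regions. Of the 22 regions with a copy, 18 belonged to ARNOLDY1, ARNOLDY2 and HELITRONY3, counting 1 that lists ARNOLDY1 with a further family. All 18 kept regions of these families had a copy, against 15 of their 106 regions without nrpd1a reads, which were not matched on level. Outside these families, where some regions list no repeat, 4 of 25 kept regions had one (16.0%), against 9 of 245 matched regions (3.67%). The regions of AT3G44580 with 214 and 75 reads had copies of 2323 and 2117 bp. Most of the 25, including those with 637, 314 and 272 reads, had none. Kept here means at least 10 reads, and the ratios of the 25 to WT ran from 0.015 in ATREP10B to 40.3 in AT2G07732. Those under 10% of WT, such as ATREP10B, had no copy. Pieces of structural, microRNA or organelle RNAs stay open: 11.6% of the 43 regions lay near such a gene or had most 24-mers in an organelle genome, against 0.465% of the matched regions, which is neither most of them nor under the 10% that had been set as excluding it. No difference between genotypes other than the loss of polymerase IV was given by the design, and with 1 library it was not tested.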
